A study of Arabidopsis thaliana with 24 samples.

How the data were processed

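Gene expression was measured by RNA-seq in whole Arabidopsis thaliana seedlings of 4 genotypes (Col-0, vq1, vq10, vq1vq10). Per the labels, seedlings grew for 14 days in MS medium with 1% sucrose under 16 h light and 8 h dark at 150 µmol. On day 15, from 4 h after lights on, they were kept for 4 h in dim light of 30 µmol at 21% or 1% oxygen. RNA came from a NucleoSpin Plant RNA kit (RIN above 8), and libraries were made from 1 µg with the MGIEasy RNA Library Prep Kit V3.0.

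The submitters' processing notes name HISAT2 2.0.4, DESeq2 and the build TAIR10 without saying which step used which. The read counter, its treatment of strand and of reads shared between genes, and any filter are not given in the sources used here. Per the file headers each library has a read count, a TPM and an FPKM for each of 23929 genes, each matched to a protein-coding gene of the TAIR10.1 annotation used here, which lists 27562 of them. The deposited read counts are expected counts (estimated reads per gene), since 525 to 581 genes per library are not whole numbers; they were rounded to whole numbers before testing. The deposited TPM sum to 999999 to 1000001 per library. The deposited TPM and FPKM were not used for tests. Genes were matched by locus identifier because 24 symbols had been turned into dates by a spreadsheet, and they are printed under the symbol of the TAIR10.1 annotation, or the locus where it has none. Positions are from TAIR10.1.

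Counts per library were 21150036 to 22645180, and the 10 most abundant genes took 11.5 to 14.2% of them. At this depth a gene with 3 reads in a group of 3 libraries lies near 0.05 CPM, and a group without reads was set to a floor of 3 reads over the group for fold bounds. Groups with 1 to 3 reads are given as a ratio with a 95% counting interval. No 2 libraries were duplicates (smallest chi-square per degree of freedom between replicates 6.14). The first principal component held 56.1% of the variance and separated the conditions, the second 5.8%. TMM factors were 1.03 to 1.108 under normoxia and 0.876 to 1.018 under hypoxia.

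Groups were taken from the labels: genotype and condition, with 3 biological replicates each. One edgeR (4.0.16, R 4.3.3) quasi-likelihood model with a mean per group was fitted to all 24 libraries after TMM normalization and the filterByExpr filter, leaving 20110 genes (common dispersion 0.0161, biological coefficient of variation 0.127, median prior degrees of freedom 6.3). It gave 17 contrasts: hypoxia against normoxia in each genotype, each mutant against Col in each condition, the difference between each mutant and Col in their response to hypoxia, and the double mutant against each single mutant in each condition. Genes with a Benjamini-Hochberg adjusted p under 0.05 in a contrast were called. Standard errors are the log2 change over the square root of its F, and intervals are 95%.

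Lists of genes were written before the data were examined: 23 lists and 5 marker lists, 401 distinct loci, all in the files; for 49 the usual symbol is not in the annotation. The lists with at least 5 tested members, 25 in all, were tested with limma camera 3.58.1 on log2 CPM with a prior count of 2 and a preset correlation of 0.01, in the contrasts other than those between mutants. Each list's adjusted p is over the lists of its contrast. The number of members called is given over all genes and adjusted over the list alone. Families of genes sharing a symbol were added after the data were seen.

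Named genes followed a rule written at the same time. It took VQ1 and VQ10, then called genes with an average log2 CPM of at least 1 whose 3 libraries of one group all lay above the 3 of the other. Of these it took the 12 largest changes in each direction for hypoxia in Col, 6 for each mutant against Col, 5 for each difference in response (without the demand on libraries), 3 for the double against each single mutant, and 8 among genes called in all 3 mutants. Hypoxia in the mutants used the genes of Col. From each list it took up to 4 called members or, where none passed, the highest expressed, and it added the 5 annotated genes on either side of VQ1 and VQ10. Other genes named as examples of lists, or because they lie outside this rule, were chosen after their values were seen.

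The alternatives tried were RLE in place of TMM factors, no low-count filter, DESeq2 1.42.0 (Wald test, same groups), a fit of the compared libraries alone, the replicate number as a block, and leaving out each library in turn. For lists they were a correlation estimated from the data, and fry, which tests whether a list moves one way on balance and not against other genes. Counts without the run of genes beside VQ10 were added after the data were seen. Whether replicate numbers pair libraries was checked with the correlation of residuals from group means. Libraries of the same condition and number had a median r of 0.10 under normoxia (13 of 18 pairs above 0, -0.10 to 0.38) and 0.12 under hypoxia (17 of 18 above 0, -0.01 to 0.32), against -0.06 for different numbers in each. Across conditions the median was -0.03 over 48 pairs. Every pair was above 0.1 for 2 comparisons, vq1vq10 against vq10 under normoxia and vq1vq10 against vq1 under hypoxia. The fit without the block was kept for all comparisons, as planned.

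The procedure was tested on simulated data of the same design with 20027 genes. In each contrast 67, 67 and 66 genes were changed 1.5-fold, 2-fold and 4-fold. They were drawn from genes outside the lists with a mean of at least 2 CPM over the groups. For vq1 against Col under normoxia edgeR recovered 52.2, 88.1 and 98.5% of genes changed 1.5-fold, 2-fold and 4-fold, with 8 unchanged genes among 168 called. DESeq2 recovered 58.2, 95.5 and 98.5%, with 25 of 195. For the difference in response between vq10 and Col edgeR recovered 19.4, 79.1 and 100%, with 4 unchanged of 136, and DESeq2 26.9, 86.6 and 100%, with 9 of 151. A list raised 1.5-fold had camera adjusted p = 5.6e-06 (0.0051 with an estimated correlation) and 0 other lists were called by camera. Genes were drawn independently of each other, so list members did not vary together. The simulation therefore does not show how the preset correlation performs on lists whose members do. The shares recovered do not apply to genes of lower level, such as VQ10. With fewer changed genes the adjusted p is harder to pass, so a count of 0 calls does not exclude differences of these sizes.

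DESeq2 gave no adjusted p for 5 genes per comparison, and for 1953 in the double mutant against vq1 under hypoxia, which count as not called. The calls between mutants were not tested by list.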

Results

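RNA-seq libraries were analysed from Arabidopsis thaliana seedlings of 4 genotypes: the accession Col-0 (Col below), the mutants vq1 and vq10, which the series title calls hypermorphic, and the double mutant vq1vq10. VQ1 and VQ10 belong to the plant family of VQ-motif proteins, many of which bind WRKY transcription factors. Seedlings were kept at 21% oxygen (normoxia) or at 1% oxygen for 4 h (hypoxia), with 3 biological replicates per genotype and condition, so that 24 libraries fell into 8 groups. Each library held 21150036 to 22645180 estimated reads over 23929 protein-coding genes, of which 20110 passed the low-count filter and were tested. Every group mean below has n = 3 and is in CPM (reads per 1000000 after TMM scaling) ± SD. A value after ± beside a log2 change is its standard error, and many changes are given without one. Adjusted p of single genes are from edgeR unless another test is named. The design asks how seedlings of each genotype respond to low oxygen, whether the mutants respond differently from Col, and whether the double mutant differs from each single mutant.

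The mutated genes were measured first. VQ10 (AT1G78410, TAIR10.1 chromosome 1, 29502506 to 29503938) was higher than in Col in both lines that carry the vq10 label. Under normoxia it rose from 0.37 ± 0.19 CPM in Col to 2.22 ± 0.23 in vq10 (log2 change 2.56 ± 0.40, adjusted p = 0.003) and 1.86 ± 0.43 in vq1vq10 (2.30 ± 0.40, adjusted p = 0.013). Under hypoxia it rose from 0.23 ± 0.13 CPM to 1.39 ± 0.31 in vq10 (2.57 ± 0.46, adjusted p = 0.023) and 1.27 ± 0.23 in vq1vq10 (2.44 ± 0.46, adjusted p = 0.031). VQ1 (AT1G17147, chromosome 1, 5863109 to 5864059) was not higher in the libraries labelled vq1 or vq1vq10: its level under normoxia was 4.20 ± 1.19 CPM in Col, 3.60 ± 0.59 in the libraries labelled vq1 and 3.15 ± 0.94 in those labelled vq1vq10. The log2 differences from Col were -0.22 (95% interval -0.77 to 0.32) and -0.42 (-0.97 to 0.14) under normoxia, and 0.12 and -0.05 under hypoxia, all with adjusted p above the threshold. VQ1 transcript level therefore did not check the vq1 part of either label, and "vq1", "vq1vq10" and "double mutant" name below the libraries that carry these labels.

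The VQ10 calls rested on 2 to 58 reads per library, and several ended when a library was left out. In vq10 under hypoxia the adjusted p was 0.13, 0.12, 0.10 and 0.098 without replicates 1 and 2 of Col and replicates 1 and 3 of vq10, and 0.23 in a fit of the compared libraries alone (0.059 in vq10 under normoxia, 0.20 and 0.17 in vq1vq10). In vq1vq10 it reached 0.15 under normoxia without replicate 1 of Col (0.11 without replicate 2 of Col, 0.098 and 0.078 without replicates 2 and 3 of vq1vq10), and 0.22 under hypoxia without replicate 1 of Col (0.21 without replicate 2 of Col, 0.13, 0.056 and 0.073 without each replicate of vq1vq10).

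**Figure D1:**
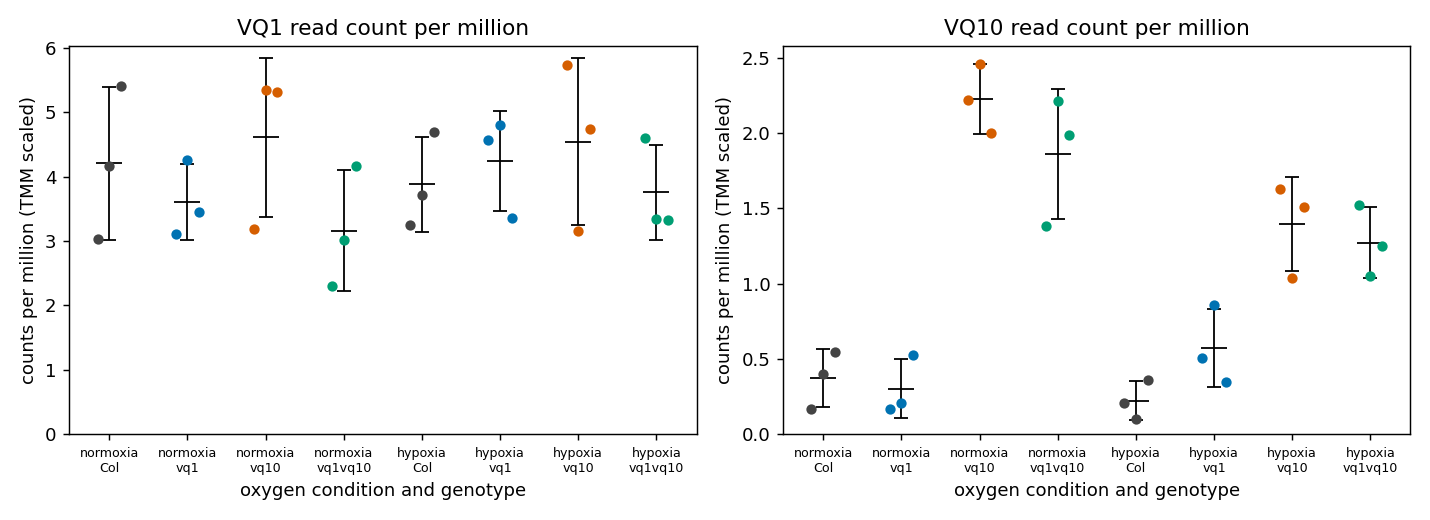
VQ1 and VQ10 in each library (points, CPM after TMM scaling) by genotype and condition, with the group mean and SD (n = 3). VQ10 lay between 1.04 and 2.46 CPM in libraries labelled vq10 or vq1vq10. It reached at most 0.55 CPM in Col and 0.86 CPM in vq1 libraries, while VQ1 overlapped between genotypes.

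In Col, 4 h of low oxygen changed 8410 of 20110 genes, 4402 upward and 4008 downward, and 1123 rose and 1056 fell at least 2-fold. Among the largest increases was ADH1, the alcohol dehydrogenase of ethanol fermentation, from 17.5 ± 11.5 to 929 ± 164 CPM (log2 change 5.73 ± 0.34, adjusted p = 1.4e-11). AT4G33070 (PDC1), a pyruvate decarboxylase of the same route, went from 7.77 ± 3.39 to 423 ± 113 CPM (5.76 ± 0.24). The aquaporin gene NIP2;1 rose from 0.64 ± 0.30 to 77.2 ± 34.8 CPM (6.89 ± 0.36), and AT2G17850 from 0.11 ± 0.09 to 37.9 ± 11 CPM (8.35 ± 0.42). AT5G10040, known as HUP9, had 1 read in the normoxic and 897 in the hypoxic libraries, a ratio of 1070 with a counting interval of 192 to 42400.

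Among the genes that fell furthest in Col was CIB1, a transcription factor gene known from blue-light signalling, with 602 reads under normoxia and 0 under hypoxia, at least 168-fold lower against a floor of 3 reads per group. PORA, which encodes a protochlorophyllide oxidoreductase of chlorophyll synthesis, fell from 21.7 ± 2.75 to 1.3 ± 0.56 CPM (-4.05 ± 0.23, adjusted p = 6.2e-12). The expansin genes EXPA16 (-3.98 ± 0.27) and EXPA7 (-3.84 ± 0.46), whose products loosen cell walls, fell as well, and so did the immune receptor gene FLS2, from 27.7 ± 2.03 to 2.60 ± 0.94 CPM (-3.40 ± 0.30, adjusted p = 7.7e-09).

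All 34 tested members of the hypoxia core response rose in Col, and all 34 also when adjusted over the list alone, with a median log2 change of 3.49 and camera adjusted p = 2.9e-29 (adjusted p = 0.0011 with an estimated correlation). AT3G10040 (HRA1) rose by 5.28 ± 0.18, LBD41 by 4.74 ± 0.18, HB1, a phytoglobin gene, by 4.57 and the ethylene response factor gene ERF73 (HRE1) by 2.16. The smallest increase in the list was that of AT3G10020, 0.67. Of 12 genes of fermentation and sugar catabolism 10 rose and 0 fell (10 and 1 when adjusted over the list alone), with SUS4 at 5.08, SUS1 at 3.76 and PDC2 at 2.03, while GAPC1 (0.02, adjusted p = 0.92) and the enolase gene LOS2 (-0.32, adjusted p = 0.082) did not pass. The median of that list was 1.77, with camera adjusted p = 7.8e-10 and an adjusted p = 0.08 with an estimated correlation. The group VII ERF and N-degron genes, which act in oxygen sensing, had 1 member higher and 3 lower of 13 (1 and 2 over the list alone), among them EBP (RAP2.3) at -0.84 and RAP2.12 at -0.40, and the list was not called (median -0.10, adjusted p = 0.36).

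**Figure D2:**
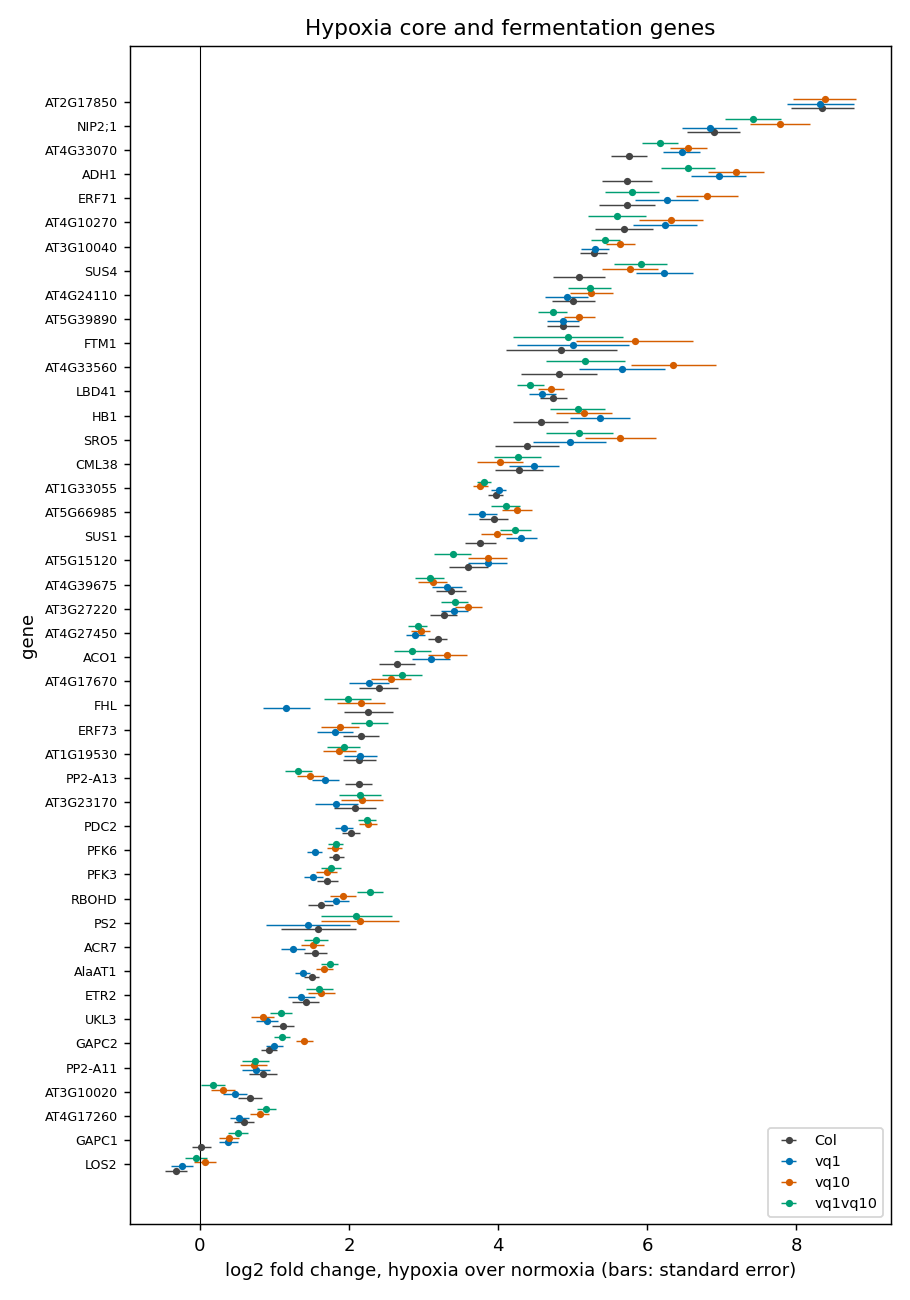
Log2 change under hypoxia against normoxia with its standard error for genes of the hypoxia core response and of fermentation in each of the 4 genotypes (n = 3 libraries per group). Fitted changes of genes with 0 to 3 reads in a group are not drawn, and the drawn points lie above 0 in each genotype apart from those of the fermentation gene LOS2 in Col, vq1 and vq1vq10.

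Stress and clock genes also rose in Col. In the heat shock list 15 of 19 members rose and 1 fell (median 1.75), including HSP17.6A at 4.06, HSFA2 at 2.84 and HSP101 at 0.96, with HSF4 falling by 0.44. In the abscisic acid and drought list 13 of 17 rose and 0 fell (14 over the list alone), including COR15A at 3.85, P5CS1 at 2.99 and RAB18 at 2.61. The circadian clock list had 10 of 15 members higher and 0 lower, with the morning-phased genes RVE1 at 4.02, CCA1 at 2.63 and RVE8 at 1.89 and the evening gene TOC1 at 0.19 (adjusted p = 0.13). Camera gave adjusted p = 0.00019, 6.8e-05 and 1.8e-05 for these 3 lists (adjusted p = 0.4, 0.4 and 0.084 with an estimated correlation). Nuclear genes of photosynthesis rose in 11 of 24 cases and fell in 0 (RCA 1.28, RBCS2B 0.71; median 0.22, adjusted p = 0.00053, and 0.45 as the adjusted p with an estimated correlation). Sugar starvation genes rose in 8 of 12 cases (9 over the list alone; ASN1 1.02, TPS11 0.85; adjusted p = 0.0018, and adjusted p = 0.4 with an estimated correlation). Flavonoid genes rose in 6 of 11 (F3H 1.49, TT4 1.05; adjusted p = 0.0048, and adjusted p = 0.08 with an estimated correlation).

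Of the lists that fell in Col, the aliphatic glucosinolate genes, which make methionine-derived defence compounds, had 8 of 10 members lower and 0 higher (9 lower when adjusted over the list alone), with CYP79F2 at -2.20, BCAT4 at -1.56 and BAT5 at -1.42 and a median of -1.17 (adjusted p = 0.0013, and adjusted p = 0.4 with an estimated correlation). Ethylene synthesis and signalling genes fell in 8 of 10 cases (ERF5 -2.52, EBF2 -1.51; adjusted p = 0.0048, and adjusted p = 0.23 with an estimated correlation). Camalexin and indole glucosinolate genes fell in 8 of 13 (CYP71A12 -2.48, CYP79B2 -1.33; 1 member rose when adjusted over the list alone), and unfolded protein response genes fell in 5 of 7 with 1 higher (BIP2 -1.07, CNX1 -0.85). Their adjusted p were 0.027 and 0.04 (adjusted p = 0.4 for each with an estimated correlation). Markers of root hairs and roots moved with these groups: 4 of 8 fell (5 over the list alone; EXPA7 -3.84, EXPA18 -2.94, SHV2 -2.44) and 0 rose, with a median of -0.93 and adjusted p = 0.0087 (adjusted p = 0.32 with an estimated correlation). The stomatal lineage markers had 0 members called of 6 in edgeR (median -0.02, adjusted p = 0.88).

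The other lists were not called in Col. Of the cell cycle genes 4 of 8 fell (CDKB1;1 -1.11; adjusted p = 0.072), of the mitochondrial dysfunction stimulon 3 of 8 rose (AT5G51440 1.75, AOX1A 0.67; adjusted p = 0.079), and of the cell wall expansion and auxin list 3 of 16 rose and 7 fell (EXPA1 1.52, XTH15 -2.78; adjusted p = 0.17). In the jasmonate list 2 of 20 rose and 4 fell (ORA59 -1.58; adjusted p = 0.78), and in the salicylic acid list 1 of 16 rose and 3 fell (NPR1 0.46, EDS1 -0.75; adjusted p = 0.78). Among the other VQ family genes 4 of 26 rose and 4 fell (PDE337 1.03, AT3G15300 -1.02; adjusted p = 0.94), and among the WRKY factors 3 of 20 rose and 2 fell (2 and 2 over the list alone; adjusted p = 0.96). The nitrate list had 2 higher and 2 lower of 9 (NIA2 0.71; adjusted p = 0.94), the iron list 2 and 2 of 17 (FER4 -0.88; adjusted p = 0.96) and the ROS list 3 and 3 of 15 (CAT2 1.53; 3 and 4 over the list alone; adjusted p = 0.96). Median, mean and test direction differed in sign for iron (0.27, 0.06, down), nitrate (-0.07, 0.06, down), ROS (0.04, -0.04, up), salicylic acid (0.14, -0.05, down) and the VQ family (0.01, 0.06, down). Seed storage, senescence and floral markers had fewer than 5 tested members and no list test; of the senescence markers SAG29 rose by 1.34 and NAC6 fell (-1.23).

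The same treatment changed 7166 genes in vq1 (3845 higher, 3321 lower), 7576 in vq10 (3921 and 3655) and 6727 in vq1vq10 (3559 and 3168). In vq1, vq10 and vq1vq10 ADH1 rose by 6.96, 7.19 and 6.55 on the log2 scale, AT4G33070 by 6.46, 6.55 and 6.17, and NIP2;1 by 6.84, 7.78 and 7.42. PORA (-3.75, -3.64 and -3.72) and FLS2 (-3.05, -2.45 and -2.05) fell. CIB1 was at least 211-fold, 214-fold and 215-fold lower, with 0 reads under hypoxia in each genotype. In all 4 genotypes 2431 genes rose and 1764 fell, and 0 genes called in all 4 by edgeR differed in direction. Between Col and the mutants 5908, 5619 and 5347 genes were called in both, of which 0, 7 and 3 changed in opposite directions, and the log2 changes correlated across genes with r = 0.85, 0.84 and 0.80 (genes are not independent replicates).

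In the mutants 34, 33 and 33 of the 34 core genes rose, with medians of 3.60, 3.68 and 3.41 (a gene without normoxic reads taken at its bound) and camera adjusted p = 3.1e-31, 3.9e-32 and 4.2e-34 (adjusted p = 0.00074, 0.00063 and 0.00045 with an estimated correlation). Fermentation genes rose in 11 of 12 cases in each mutant (adjusted p = 7.6e-12, 1.5e-13 and 2e-14, and adjusted p = 0.042, 0.016 and 0.016 with an estimated correlation). Flavonoid genes rose in 6, 9 and 7 of 11 cases, F3H by 1.45, 1.88 and 1.76 and TT4 by 1.44, 1.76 and 1.29 (adjusted p = 0.0036, 3.9e-05 and 0.00036, and adjusted p = 0.053, 0.0067 and 0.016 with an estimated correlation). Aliphatic glucosinolate genes fell in 4, 1 and 0 of 10 cases, and the list was not called (adjusted p = 0.068, 0.98 and 0.9). Over the 25 lists camera called 13 in Col, 11 in vq1, 10 in vq10 and 9 in vq1vq10, of which 1, 2, 3 and 3 held with an estimated correlation.

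No single gene passed the direct test of whether its hypoxia response differed from Col: edgeR called 0 genes for vq1, vq10 and vq1vq10, with 682, 1654 and 1637 genes at an unadjusted p under 0.05 and smallest adjusted p of 1, 0.595 and 0.244. DESeq2 called 0, 0 and 2. Gene lists did differ at the preset correlation. The aliphatic glucosinolate genes responded less negatively in vq10 (median difference 1.27, adjusted p = 2e-09) and vq1vq10 (1.09, adjusted p = 8.9e-09), and 8 and 9 of the 10 members passed when adjusted over the list alone. These list calls were lost with an estimated correlation (adjusted p = 0.19 in vq10 and 0.23 in vq1vq10), as were all other list calls of these comparisons. In vq1 the median difference of this list was 0.53. Each mutant's difference subtracts the same Col libraries, so their agreement is not independent. For CYP79F1 the difference from Col was 2.14 in vq10 and 2.12 in vq1vq10, for BAT5 1.32 and 1.25 and for MYB28, a regulator of the pathway, 0.67 and 0.50. The mean log2 CPM of the 10 genes was 4.67 ± 0.41 under normoxia and 3.49 ± 0.15 under hypoxia in Col, against 4.30 ± 0.35 and 4.36 ± 0.04 in vq10 and 4.38 ± 0.53 and 4.39 ± 0.05 in vq1vq10.

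**Figure D3:**
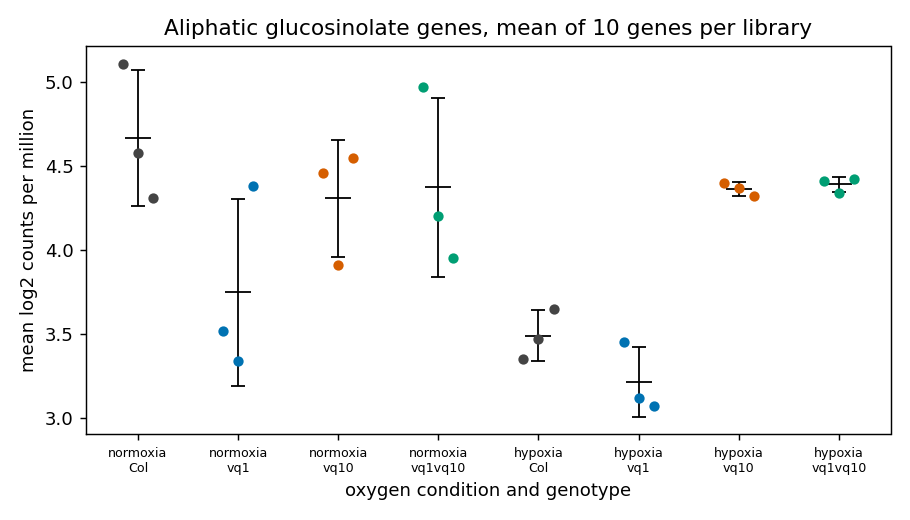
Mean log2 CPM of the 10 aliphatic glucosinolate genes in each library (points) by genotype and condition, with the group mean and SD (n = 3). Under hypoxia Col and vq1 libraries averaged 3.49 and 3.21, and vq10 and vq1vq10 libraries 4.36 and 4.39.

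Other lists also responded differently at the preset correlation. Salicylic acid defence genes responded more positively in vq1 (median 0.56, adjusted p = 0.0011) and vq1vq10 (0.91, adjusted p = 2.1e-05), with differences of 0.54 and 0.95 for PAD4 and of 1.84 and 1.99 for PBS3, and the adjusted p was 0.83 and 0.25 with an estimated correlation. Reads of PR1, the usual marker of this response, varied widely within groups (2307, 275 and 69 in the hypoxic vq1vq10 libraries). Sugar starvation genes responded less in vq10 (-0.36, adjusted p = 9.1e-07) and vq1vq10 (-0.48, adjusted p = 3.3e-06), with differences of -0.79 and -0.70 for ASN1, and the adjusted p was 0.28 and 0.25 with an estimated correlation. Flavonoid genes responded more in vq10 (0.70, adjusted p = 0.0024, and adjusted p = 0.11 with an estimated correlation), and photosynthesis genes less in vq1vq10 (-0.28, adjusted p = 1.6e-07, and adjusted p = 0.38 with an estimated correlation).

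Under normoxia 16 genes differed between vq1 and Col, 5 higher and 11 lower. MRD1 fell from 19.1 ± 0.62 to 0.32 ± 0.21 CPM (-5.86 ± 0.38, adjusted p = 4.5e-09), and HEI10, which encodes a factor of meiotic crossing over, from 10.5 ± 0.89 to 1.97 ± 0.46 CPM (-2.41 ± 0.19, adjusted p = 1.1e-07). The orphan gene QQS, known from starch metabolism, fell from 7.71 ± 0.63 to 1.44 ± 0.90 CPM (-2.43 ± 0.38, adjusted p = 0.0033). BCAT-2, a branched-chain aminotransferase gene, rose from 56.5 ± 9.09 to 132 ± 25.9 CPM (1.22 ± 0.18, adjusted p = 0.0015), AT3G56210 from 26.7 ± 3.18 to 57.2 ± 1.22 CPM (1.1 ± 0.09) and AT2G03640 from 48.9 ± 1.55 to 95.7 ± 8.72 CPM (0.97 ± 0.12). AT2G31440 (-0.92) and AT5G25520 (-0.65) fell. AT1G75945, chosen after its values were seen, rose from 0.35 ± 0.32 to 7.21 ± 1.62 CPM (4.36 ± 0.60, adjusted p = 0.0013). The nearest tested genes on either side of VQ1, AT1G17145 (0.17 ± 0.11) and AT1G17160 (0.11 ± 0.10), did not pass, and AT1G17150 between VQ1 and AT1G17160 had too few reads to be tested.

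Camera called 5 lists in this comparison. The aliphatic glucosinolate genes were lower with a median of -0.91 (adjusted p = 3.6e-11, and adjusted p = 0.23 with an estimated correlation), 9 of 10 when adjusted over the list alone and 0 over all genes in edgeR, and their mean log2 CPM was 3.75 ± 0.56 against 4.67 ± 0.41 in Col. Sugar starvation genes were higher (median 0.33, adjusted p = 3.9e-07, and adjusted p = 0.36 with an estimated correlation). Fermentation genes were lower (-0.25, adjusted p = 8.9e-05; 6 of 12 over the list alone), as were hypoxia core genes (-0.25, adjusted p = 0.02), and clock genes were higher (0.08, adjusted p = 0.045); for these 3 the adjusted p was 0.43, 0.56 and 0.56 with an estimated correlation. DESeq2 called 49 genes, against 16 in edgeR.

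In vq10 under normoxia 12 genes differed from Col, 4 higher and 8 lower. Besides VQ10, AT5G24240 rose from 0.84 ± 0.31 to 7.61 ± 1.74 CPM (3.17 ± 0.37, adjusted p = 6.5e-05), AT3G56210 by 0.97 ± 0.09 and AT2G03640 by 0.91 ± 0.12. MRD1 (-5.53 ± 0.37, adjusted p = 7.4e-09), QQS (-3.53 ± 0.42) and HEI10 (-2.23 ± 0.19) fell. The other large decreases were neighbours of VQ10: AT1G78460 went from 171 ± 19.2 to 8.43 ± 14.4 CPM (-4.34 ± 0.82, adjusted p = 0.042), CYP708A3, a cytochrome P450 gene, changed by -3.97 ± 0.52 (adjusted p = 0.00026), RIP4 by -4.36 ± 0.55 (adjusted p = 0.00059) and AT1G78420 (DA2) by -3.87 ± 0.64 (adjusted p = 0.011). The call of AT1G78460 ended without any 1 of 5 libraries (adjusted p = 0.067, 0.12 and 0.064 without replicates 1, 2 and 3 of Col, 0.15 and 0.19 without replicates 1 and 2 of vq10), and that of AT1G78420 without replicate 1 or 2 of vq10 (0.05 and 0.064). In a fit of the compared libraries alone these and CYP708A3 missed the threshold (0.97, 0.58 and 0.11).

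In vq1vq10 under normoxia 13 genes differed, 5 higher and 8 lower, with the same named genes among them. VQ10, AT5G24240 (3.25 ± 0.37), AT3G56210 (1.15 ± 0.09) and AT2G03640 (0.85 ± 0.12) rose, as did FLC, the repressor of flowering (1.14 ± 0.20, adjusted p = 0.018). MRD1 (-5.30 ± 0.36), QQS (-3.76 ± 0.43) and HEI10 (-2.44 ± 0.19) fell. Next to VQ10, AT1G78420 went from 1840 to 0 reads, at least 600-fold lower, RIP4 was at least 77.6-fold lower, AT1G78460 went from 171 ± 19.2 to 0.10 ± 0.10 CPM, and CYP708A3 changed by -5.05 ± 0.58 (adjusted p = 3.6e-05). The FLC call ended without replicate 2 or 3 of Col (adjusted p = 0.27 and 0.15) or replicate 2 or 3 of vq1vq10 (0.06 and 0.22), and in a fit of the compared libraries alone (0.44).

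The lowered neighbours lay in a run of 9 annotated genes from 29504532 to 29530669 on chromosome 1, next to VQ10. Of 7 that could be tested, 5 were called lower in vq1vq10 and 4 in vq10 under normoxia; ATGA2OX1 and AT1G78476 were not called, and AT1G78470 had 0 reads in Col. Summed over the run, normoxic levels were 219 ± 14.7 CPM in Col, 250 ± 12 in vq1, 11.5 ± 19.2 in vq10 and 0.611 ± 0.399 in vq1vq10. Hypoxic levels were 198 ± 25, 189 ± 5.75, 9.66 ± 7.80 and 0.94 ± 0.32 CPM in the same order. In vq10 the sum differed between libraries, with 6, 14 and 794 reads under normoxia and 15, 270 and 297 under hypoxia, or 0.115 to 15.4% and 0.398 to 7.8% of the Col mean. The 17 other tested genes within 60 kb of VQ10, outside the run, had a median log2 difference of -0.05 in vq1vq10 under normoxia. Without the run, 8 genes were called in vq10 and 8 in vq1vq10 under normoxia.

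**Figure D4:**
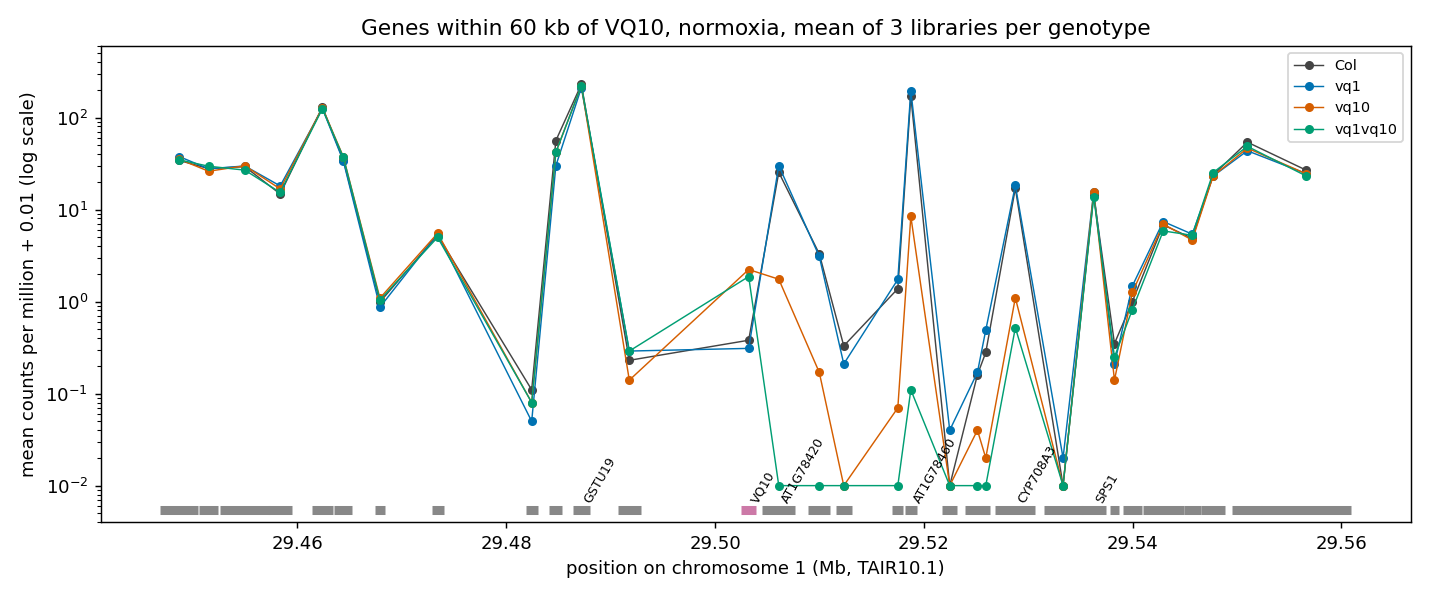
Normoxic mean CPM + 0.01 (log axis) of the genes within 60 kb of VQ10 in each genotype, by position on chromosome 1 (TAIR10.1, Mb; n = 3 per genotype). The genes of the run to the right of VQ10 that had reads in Col lie below Col in vq10 and vq1vq10, while vq1 follows Col.

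None of the list calls in vq10 and vq1vq10 under normoxia held with an estimated correlation, where the adjusted p lay between 0.097 for flavonoids in vq10 and 0.7 for aliphatic glucosinolates in vq1vq10. Gene lists called at the preset correlation in vq10 were sugar starvation (higher, median 0.28, adjusted p = 3e-07), fermentation (-0.18, adjusted p = 0.00035), aliphatic glucosinolates (-0.42, adjusted p = 0.0021), flavonoids (-0.34, adjusted p = 0.0021), the hypoxia core response (-0.15), the unfolded protein response (-0.22), the jasmonate list (-0.12, adjusted p = 0.03) and the root markers (-0.47, adjusted p = 0.017). In vq1vq10 they were sugar starvation (0.29, adjusted p = 2.2e-06), iron homeostasis (-0.34, adjusted p = 0.018), jasmonate (-0.19, adjusted p = 0.018) and aliphatic glucosinolates (-0.24, adjusted p = 0.035).

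Under hypoxia 17 genes differed from Col in vq1 (5 higher, 12 lower), 13 in vq10 (4 and 9) and 17 in vq1vq10 (6 and 11). In vq1, vq10 and vq1vq10 MRD1 (-6.52, -6.78 and -5.11), QQS (-2.88, -3.50 and -3.10) and HEI10 (-1.47, -0.99 and -1.02) fell, and AT3G56210 rose (1.16, 1.24 and 1.19). In vq1 AT2G31440 (-0.91 ± 0.12) and AT1G24290 (-0.96 ± 0.15) fell and AT2G03640 rose (0.90 ± 0.12). The receptor-like kinase gene CRK40 rose in vq10 (1.78 ± 0.25, adjusted p = 9e-04) and vq1vq10 (1.52 ± 0.25, adjusted p = 0.0051), as did AT5G24240 (2.93 ± 0.42 and 3.20 ± 0.41). In vq1vq10 AT5G35940 (1.83 ± 0.29, adjusted p = 0.005) and OPCL1, a gene of jasmonate synthesis (0.76 ± 0.12, adjusted p = 0.0049), rose. The run beside VQ10 stayed low, with AT1G78420 at -4.46 ± 0.67 in vq10 and at a ratio of 728 (counting interval 249 to 3530) between Col and vq1vq10.

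The hypoxic counts depended on single libraries. Without replicate 3 of hypoxic Col 137 genes were called in vq1 and 338 in vq1vq10, against 10 and 10 without replicate 1 of hypoxic Col; vq1 also gave 10 without replicate 2 of Col and 11 without replicate 2 or 3 of vq1. DESeq2 called 26, 25 and 47 genes, and a fit of the compared libraries alone 3 in vq1 and 6 in vq10. That fit ended the calls of AT1G24290, AT2G31440, AT2G03640, HEI10 and QQS in vq1 (adjusted p = 0.59, 0.18, 0.15, 0.18 and 0.099), AT5G24240, CRK40 and HEI10 in vq10 (0.091, 0.17 and 0.43), and CRK40, OPCL1 and HEI10 in vq1vq10 (0.082, 0.14 and 0.19). The HEI10 call ended in vq10 without any 1 of the 6 libraries (adjusted p = 0.13, 0.087 and 0.18 without replicates 1, 2 and 3 of Col, 0.091, 0.17 and 0.26 without those of vq10). In vq1vq10 it ended without replicate 1 or 2 of Col (0.10 and 0.072) or of vq1vq10 (0.23 and 0.21). Without replicate 1 of Col those of CRK40 and AT5G35940 in vq1vq10 ended as well (0.073 and 0.083).

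None of the hypoxic list calls against Col held with an estimated correlation, the lowest adjusted p being 0.15 for aliphatic glucosinolates and photosynthesis in vq1vq10, with 0.46 for aliphatic glucosinolates in vq10 and 0.99 for the lists in vq1. At the preset correlation the aliphatic glucosinolate genes stood above Col in vq10 (median 0.82, adjusted p = 8.3e-09; 8 of 10 over the list alone) and vq1vq10 (0.82, adjusted p = 2.8e-09; 9 of 10), and below Col in vq1 (-0.34, adjusted p = 0.038). Photosynthesis genes were lower in vq1vq10 (-0.30, adjusted p = 2.8e-15; 15 of 24 over the list alone), where salicylic acid (0.68, adjusted p = 5.2e-06), WRKY (0.38), heat shock (0.47), camalexin (0.45), jasmonate (0.25), mitochondrial (0.36) and fermentation genes (0.23) were higher and sugar starvation genes lower (-0.19, adjusted p = 0.039). In vq10 camalexin (0.31) and iron genes (0.47) were higher and clock (-0.18) and sugar starvation genes (-0.14) lower. In vq1 salicylic acid genes were higher (0.55), and hypoxia core (-0.27, adjusted p = 0.00029) and fermentation genes (-0.15) were lower.

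Genes called against Col in all 3 mutants numbered 5 under normoxia, 2 higher (AT3G56210, chromosome 3, 20852380 to 20855610, and AT2G03640) and 3 lower (MRD1, chromosome 1, 19963047 to 19964712; HEI10, 19963267 to 19966952; QQS, chromosome 3, 12349047 to 12349933). Under hypoxia they numbered 4, with 1 higher (AT3G56210) and 3 lower (MRD1, HEI10 and QQS). MRD1 and HEI10 overlap on opposite strands, and whether the counting used strand is not given in the sources used here, so their reads cannot be told apart by strand. All 3 comparisons share the Col libraries. In 20 simulated sets of unchanged groups against shared controls 0 genes were called in all 3. Independent lists would give 0.00099 to 0.0066 shared calls per pair and direction, which is no baseline for comparisons that share controls. Under normoxia vq10 and vq1vq10 shared 4 higher and 7 lower genes, vq1 and vq10 shared 2 and 3, and vq1 and vq1vq10 shared 2 and 3. Log2 differences from Col correlated across genes with r = 0.45 to 0.49 under normoxia and 0.44 to 0.67 under hypoxia, against 0.49 to 0.50 in the simulated sets. Their covariance was 0.0483 to 0.0502 under normoxia against a simulated 0.0354 to 0.0362, and 0.0587 (vq1 and vq10), 0.0789 (vq1 and vq1vq10) and 0.108 (vq10 and vq1vq10) under hypoxia against a simulated 0.0385 to 0.039. Col had 3 libraries per condition, too few to split, so part of the excess may come from the shared controls.

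Between the double mutant and vq10 edgeR called 0 genes under normoxia and 0 under hypoxia (467 and 1853 at an unadjusted p under 0.05), and DESeq2 called 0 and 20. Between the double mutant and vq1, 24 genes differed under normoxia (14 higher, 10 lower) and 21 under hypoxia (14 and 7). AT5G24240 was higher in vq1vq10 by 3.75 ± 0.39 (adjusted p = 5.1e-05) and 4.50 ± 0.48 (adjusted p = 7.1e-05), and AT5G35940 by 2.49 ± 0.34 and 2.37 ± 0.31. VQ10 was higher under normoxia (2.57 ± 0.41, adjusted p = 0.0036) and did not pass under hypoxia (1.14 ± 0.40, adjusted p = 0.34), where it stood at 0.57 ± 0.26 CPM in vq1. Under hypoxia BAT5, a transporter gene of glucosinolate synthesis, was higher by 1.48 ± 0.23 (adjusted p = 0.0026). CYP708A3 was lower (-5.15 and -4.65), and AT1G78420 was at least 710-fold lower under normoxia. The 5 genes called in all 3 mutants had 0 calls between the double mutant and either single mutant in edgeR. The VQ10 call ended without replicate 1 or 2 of vq1 (adjusted p = 0.058 for each), the counts fell to 15 without replicate 3 of normoxic vq1vq10 and 13 without replicate 1 of hypoxic vq1vq10, and under hypoxia DESeq2 called 81 genes and a fit of the compared libraries alone 116.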

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

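The tests of a single library, of correlated list members and of a genotype effect below were chosen after the results were seen; the list tests, the estimated correlation and the other groupings of libraries were planned.

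For 22 combinations of a gene list and a mutant the response to hypoxia differed from that of Col in a test of the difference itself, at the preset correlation. Values are the median difference of the log2 responses. In vq1 they were aliphatic glucosinolates 0.53, salicylic acid defence 0.56, unfolded protein response 0.18, photosynthesis -0.14 and sugar starvation -0.19. In vq10 they were aliphatic glucosinolates 1.27, flavonoid and anthocyanin synthesis 0.70, camalexin and indole glucosinolates 0.46, jasmonate 0.38, fermentation and sugar catabolism 0.29, circadian clock -0.24 and sugar starvation -0.36. In vq1vq10 they were aliphatic glucosinolates 1.09, salicylic acid defence 0.91, heat shock 0.67, camalexin and indole glucosinolates 0.60, mitochondrial dysfunction stimulon 0.48, jasmonate 0.44, fermentation and sugar catabolism 0.29, circadian clock -0.18, photosynthesis -0.28 and sugar starvation -0.48. None of the 22 held with an estimated correlation, where the smallest adjusted p was 0.11 for flavonoids in vq10. At the level of genes edgeR called 0 in each mutant (682, 1654 and 1637 at an unadjusted p under 0.05; DESeq2 0, 0 and 2), and other groupings gave up to 1, 9 and 7. With a real count of 0 in edgeR all 20 groupings drawn for each give at least as many, so these counts decide nothing.

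The aliphatic glucosinolate genes (CYP79F1, BCAT4, BAT5, MYB28 and 6 others) were lower as a list in Col under hypoxia (adjusted p = 0.0013, and adjusted p = 0.4 with an estimated correlation) and did not pass as a list in vq1, vq10 or vq1vq10 (adjusted p = 0.068, 0.98 and 0.9). No single library brought the median difference under 0.5 of its value: the lowest was 1.05 in vq10, without replicate 1 of normoxic Col, and 0.87 in vq1vq10, without replicate 3 of normoxic vq1vq10. Both differences subtract the same Col libraries, so their agreement is not independent, and the median difference in vq1 was also positive (0.53). Members that vary together between libraries are a candidate explanation of the small p at the preset correlation, since with an estimated correlation the adjusted p was 0.19. An effect of the genotype on the response, with a median of 1.09 in vq1vq10, stays open, since replicates of 3 libraries did not pass at that correlation.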

How the results depend on the processing

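The alternatives were chosen before the data were examined, apart from the counts without the run of genes beside VQ10. RLE factors, no low-count filter and the replicate block kept all counts of calls within 1.5 times and the interactions at 0 in edgeR (682, 1654 and 1637 at an unadjusted p under 0.05; DESeq2 0, 0 and 2). With the block, vq1, vq10 and vq1vq10 differed from Col in 17, 14 and 14 genes under normoxia and 14, 13 and 22 under hypoxia. As a hint from the data, libraries with the same number deviated together within a condition (median r 0.10 under normoxia and 0.12 under hypoxia) and not across conditions (-0.03). The block gave each number the same effect in both conditions, so it could not fully take up deviations shared within a single condition. A block by number and condition was not fitted. Every pair was above 0.1 for 2 comparisons, vq1vq10 against vq10 under normoxia (0 genes with the block in edgeR) and vq1vq10 against vq1 under hypoxia (17 with the block, 21 without).

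DESeq2 called 49 genes in vq1 under normoxia, 26, 25 and 47 in vq1, vq10 and vq1vq10 under hypoxia, 2 for the response of vq1vq10, 81 for vq1vq10 against vq1 and 20 for vq1vq10 against vq10 under hypoxia. A fit of the compared libraries alone called 3 in vq1 and 6 in vq10 under hypoxia, 1 for the response of vq1vq10 and 116 for vq1vq10 against vq1 under hypoxia. Without the run 8 genes were called in vq1vq10 under normoxia and 8 in vq10 under hypoxia, by construction. Camera made 101 list calls at the preset correlation and 9 with an estimated correlation. Fry made 61, of which 17, 16, 13 and 14 were for hypoxia in Col, vq1, vq10 and vq1vq10, 1 was for vq10 against Col under hypoxia, and 0 were for differences in response. Leaving out 1 library gave 10 (without replicate 1 or 2 of hypoxic Col) to 137 (without replicate 3) for vq1 and 10 (without replicate 1) to 338 (without replicate 3) for vq1vq10 against Col under hypoxia. For vq1 it also gave 11 without replicate 2 or 3 of hypoxic vq1. For vq1vq10 against vq1 it gave 13 (without replicate 1 of hypoxic vq1vq10) to 19 under hypoxia and 15 (without replicate 3 of normoxic vq1vq10) to 20 under normoxia. Direction turned for VQ1 in vq1vq10 under hypoxia (-0.22 to 0.11; above 0 without replicate 3 of Col or replicate 2 or 3 of vq1vq10), VQ1 in vq10 under normoxia (-0.05 without replicate 1 of Col, to 0.35), VQ10 in vq1 under normoxia (-0.92 to 0.10; above 0 without replicate 3 of Col or replicate 1 of vq1) and OLEO1 under hypoxia in vq10 (-0.11 without replicate 2 of hypoxic vq10, to 3.23). Apart from the run, the cause was not tested. Depth limits the precision of VQ10, with 2 to 58 reads per library.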

Other observations

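The tests of this part were chosen after the results were seen, apart from the other groupings of libraries.

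The run of genes beside VQ10, among them AT1G78420, AT1G78460, RIP4 and CYP708A3, was low in all libraries labelled vq10 or vq1vq10. A lower scaling or depth over the whole region would lower the flanking genes too, and their median log2 difference in vq1vq10 was -0.05. The run was set after its levels were seen, so this median partly follows from that choice. A change of the segment in these lines against the reference and lowered transcription with the segment in place cannot be told apart without DNA data. The highest run level in the 12 libraries was 15.4% of the Col mean, and 5 of the tested genes of the run were called lower in vq1vq10, which either would give. The uneven level between vq10 libraries (6 to 794 reads under normoxia) may come from a mixture of plants, which was not tested.

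MRD1, HEI10, QQS and AT3G56210 differed from Col in all 3 mutants under both conditions, and AT2G03640 under normoxia. Chance from the shared Col libraries, as independent noise per gene, gave 0 genes called in all 3 in 20 simulated sets. The sets were drawn from the fitted spread and called with the same model, so a count near 0 was set in advance. These sets held no deviation common to the Col libraries, so they cannot speak to that. Reads of MRD1 counted for the overlapping HEI10 would keep the ratio of their losses only if a fixed share were counted so. HEI10 lost 8.43 CPM and 3.01 CPM under normoxia and hypoxia while MRD1 lost 18.7 and 18.7, and the ratios differed by 0.289. How the counter divides shared reads is not given, so this difference cannot decide the question. A difference of the Col plants from the parent line of the mutants stays open, with 0 of the 5 genes called between the double and a single mutant in edgeR over 4 comparisons, and it cannot be told apart from an effect common to the mutants. QQS is known to vary between Col lines through DNA methylation, which was not measured here.

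Of 11 genes that differed from Col in vq1 under normoxia and are not among the 5 called in all 3 mutants, such as AT2G31440 and AT5G25520, the median kept 79.6% of its size in vq1 under hypoxia and 9.42% in vq1vq10 under hypoxia. All 11 had the same sign in vq1 and 6 in vq1vq10. These genes were called in vq1 and not in vq1vq10 under normoxia, so the choice favours a small share in vq1vq10. Levels in the hypoxic libraries had no part in the choice, apart from the common estimate of the spread. As a median, the difference between vq1 and vq1vq10 was thus seen again in separate libraries, but not for each gene. The hypoxic gap was smallest for PAO3 (-0.13 in vq1 and -0.10 in vq1vq10) and BCAT-2 (0.38 and 0.21). In vq1 under normoxia these 2 had stood at -0.62 and 1.22. The gap was not tested over the 11 genes together, and no cause was tested. AT1G75945, chosen after its values were seen, had 110 to 135 reads in hypoxic vq1 libraries, 0 to 3 in vq1vq10 and 1 to 7 in Col. The hypoxic vq10 libraries had 6, 36 and 13, and held 15, 270 and 297 reads of the run beside VQ10. Normoxic vq10 libraries had 12, 2 and 27, with 6, 14 and 794 reads of the run, against 17, 4 and 4 in normoxic Col. The excess over Col thus lay in the vq10 libraries that kept most reads of the run. Whether it belongs to vq10 or to a mixture of plants was not tested.

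Among 129 families of genes sharing a symbol, formed after the data were seen, arabinogalactan proteins (AGP, 15 of 27 lower, 0 higher, median -0.78), fasciclin-like arabinogalactan proteins (FLA, 13 of 14 lower, -0.73), xyloglucan endotransglucosylases (XTH, 16 of 25 lower, 3 higher, -1.25) and laccases (LAC, 9 of 13 lower, -1.25) fell in Col under hypoxia. Kinases of the CIPK family (13 of 19 higher, 1 lower, 0.59) and peroxisome biogenesis genes (PEX, 12 of 19 higher, 0.28) rose. The camera adjusted p of the families were 0.00048, 0.00048, 0.0016, 0.0027, 0.0018 and 0.0027, and 0.52, 0.52, 0.44, 0.44, 0.44 and 0.44 as adjusted p with an estimated correlation. In the same comparison 4 of 8 root hair and root markers fell (median -0.93, EXPA7 -3.84; adjusted p = 0.0087, and adjusted p = 0.32 with an estimated correlation) beside these families, and a lower share of root RNA was not tested as their source.

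Groupings of the same 6 libraries number 10, the real one included, too few for a share under 0.05. For hypoxia in Col, vq1, vq10 and vq1vq10 1 of 10 gave as many genes in each, with 8410, 7166, 7576 and 6727 for the real grouping and at most 0, 1, 3 and 0 for the others. Against Col under normoxia vq1 gave 16 and vq10 12 (1 of 10 in each, highest other 0 and 0), and vq1vq10 13 (2 of 10, highest other 16). Under hypoxia vq1 gave 17, vq10 13 and vq1vq10 17 (2 of 10 in each). The highest other counts were 136, 43 and 32, several times the real count for vq1 and vq10. The grouping with 136 put replicates 1 and 2 of Col with replicate 1 of vq1. It set replicate 3 of Col apart, as did that with 32, while that with 43 set replicate 2 of Col apart. These 2 Col libraries had the largest chi-square per degree of freedom between replicates, 43.73. The cause was not tested. Between vq1vq10 and vq1 the real grouping gave 24 and 21 (1 of 10 in each, highest other 1 and 3), and between vq1vq10 and vq10 0 and 0 in edgeR (467 and 1853 at an unadjusted p under 0.05; DESeq2 0 and 20), where all 10 groupings give at least as many whatever the data, with 0 and 1 for the highest other.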
